A study of Homo sapiens with 2 samples.

How the data were processed

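RNA was measured by sequencing in 2 libraries of DLD1, a human colorectal adenocarcinoma cell line. The labels assign 1 library to the control (wild type) and 1 to the knockout of HERV-R, a human endogenous retrovirus. Both carry the same protocol text, in which vectors for Cas9 and a guide RNA were transfected and colonies were then selected with hygromycin. Which vectors the control received, and whether each library came from a single clone, is not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a directional (strand-marking) kit. The control library holds 21881122 counts and the knockout-labelled library 16406308. Whether polyadenylated RNA was selected or ribosomal RNA removed is not given in the sources used here, and neither is the position of the guide.

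Each library has a table of raw counts per gene that the authors deposited, with whole numbers and no normalization. Per the submitters' processing notes, reads were aligned with TopHat to GRCh38. The version, the counting program, the annotation, the use of strand in counting and any read filter are not given in the sources used here. Each table holds 58173 rows and the row order was the same in both. The gene symbols repeat: 2687 symbols stand on more than 1 row, 8458 rows in all, which carry 0.445% of all counts. Rows of 1 symbol were summed, which left 52402 symbols. No row lacked a gene name, and 147 symbols had counts on more than 1 row. Reads that map equally well to such copies, to processed pseudogenes or to near-identical paralogs can be lost or split by the counting, so values of HLA genes, keratins, ribosomal proteins and EEF1A1 are less certain than their counts make them look.

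Counts were scaled by the library total to counts per 1000000 (CPM). The log2 ratio was that of the knockout-labelled library over the control after a pseudocount of 1 CPM was added to both, which understates changes of genes near 1 CPM. Genes with a mean of at least 1 CPM over the 2 libraries were compared, 12644 in all, and a gene passed the size rule at a log2 ratio of at least 1 or at most -1. With 1 library per group there was no spread between replicates, so no test of the knockout was possible and no p-value is given. Folds of single genes are ratios of CPM without a pseudocount, with exact 95% intervals (Clopper-Pearson, conditional on the summed count). These intervals and the floors cover counting error only. PCR duplicates are not independent molecules, so the intervals are too narrow where duplicates were counted. They describe the 2 libraries and do not say how far other cultures would differ. A count of 0 was read as up to 3 counts, which is 0.137 CPM in the control and 0.183 CPM in the knockout-labelled library.

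The genes to name and 32 gene lists were fixed before the data were examined. Named genes were the targeted locus, the 10 highest and the 10 lowest log2 ratios among genes with a mean of at least 5 CPM (without unnamed loci, small RNA genes, Y-linked genes and XIST), and up to 2 members at each end of each list that passed the size rule. Where no member of a list passed, its 2 most abundant members stand as values. Any other gene in the text was chosen after its values were seen. Some genes that this rule names are not reported here. For each list with at least 5 measured members, the median log2 ratio was set against the medians of 10000 random gene lists of the same size, matched on mean expression in 20 bins. This describes the 2 libraries and is not a test of the knockout. A further 6 lists, a ZNF gene set and the look at chromosomes were added after the data had been seen and are used only in the additional observations.

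The procedure was tested on simulated data. Poisson counts drawn for all genes from the pooled profile, at the real library totals, gave a mean of 0.01 genes at least 2-fold higher and 0.02 genes at least 2-fold lower over 100 simulated pairs. These pairs hold counting error only and no difference between cultures. They do not tell how many genes would pass between 2 cultures of the same genotype. Among 200 genes changed by known folds in the simulated knockout-against-control comparison of 12644 genes, 98% of those made 3-fold higher, 100% of those made 4-fold higher, 88% of those made 3-fold lower and 90% of those made 4-fold lower passed the rule. A simulated list of 30 genes raised 1.5-fold lay at percentile 100 of the random lists, and 13 of 200 unchanged lists lay outside the central 95%.

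Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum mean of 5 CPM, size rules of 1.5-fold and 3-fold, and scaling by the trimmed mean of M values (TMM), by the upper quartile and by the median of gene ratios. Library totals without ribosomal RNA, protein-coding genes only, symbols on a single row only and the omission of chromosome 10 were added after the data had been seen. Gene positions come from a RefSeq gene table of GRCh38.p14, in which 46377 of the 52402 symbols were found, and from GENCODE release 29 on GRCh38 for the targeted gene. Neither is known to be the annotation the authors counted on. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and edgeR 4.0.16 in R 4.3.3 for the scaling factors alone.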

Results

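Gene expression was measured by RNA sequencing in DLD1 cells, a human colorectal adenocarcinoma line. Control cells were compared with cells labelled as a knockout of the endogenous retrovirus HERV-R. The study's title places the comparison in the context of tumorigenic properties of colorectal cancer cells. There was 1 library per group and so no replicate check of any difference. The control library held 21881122 counts on 19760 gene symbols, and the library labelled knockout 16406308 counts on 19380 symbols. Nuclear ribosomal RNA took 3.32% of the counts in the control and 3.19% in the library labelled knockout, and the 10 most abundant symbols took 8.28% and 7.05%.

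The genotype label names HERV-R only. The targeted gene was taken to be ERV3-1, which encodes the HERV-R envelope (env) protein. It lies on the minus strand of chromosome 7 (GRCh38, 64990809 to 65006743), and its env coding sequence (64991215 to 64993026) lies within exon 2. ERV3-1 RNA was not lower in the library labelled knockout. It had 127 counts (5.80 CPM) in the control and 125 (7.62 CPM) there, a ratio of 1.31 (95% counting interval 1.02 to 1.69). With each other scaling the lower bound falls below 1, as every log2 ratio shifts by -0.12 to -0.16. The read-through gene ERV3-1-ZNF117 had 10.1 CPM in the control and 10.6 CPM in the library labelled knockout, a ratio of 1.06 (0.860 to 1.29). ZNF117, a zinc finger gene that overlaps both, had 0 counts in the control and 46 in the library labelled knockout (2.80 CPM). Set against a floor of 3 counts (0.137 CPM) in the control, ZNF117 was 20.5-fold higher. The exact counting interval, which also covers the error of the 46 counts, had a lower bound of 15.97-fold. Reads in the shared sequence can be assigned to any of these rows, so the split is uncertain. Summed, the 3 rows had 15.86 and 21.03 CPM, a ratio of 1.33 (1.14 to 1.54). A count over the whole gene does not see a small insertion or deletion, and the guide's position is not given in the sources used here, so these values neither show nor exclude an edit. Every direction below rests on the label of this knockout-labelled library.

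Among the neighbours of ERV3-1 on chromosome 7, CRCP was 2.20-fold higher in the knockout-labelled library (22.7 against 49.98 CPM; counting interval 1.97 to 2.47). Of the 12 measured genes of this locus list, 2 were at least 2-fold higher, 0 were lower by that much and 10 lay between. Of the other retroviral genes, 3 were measured and 2 were higher. ERVMER34-1, which encodes the envelope protein of another endogenous retrovirus, had 5.99 CPM in the control and 26.2 CPM in the knockout-labelled library (4.37-fold; 3.58 to 5.35). ERVK3-1 had 15.2 and 32.4 CPM (2.13-fold; 1.85 to 2.45). CRCP and ERVK3-1 stood just under the 2-fold rule with each other scaling (log2 ratios of 0.99 and 0.93 with TMM) and with a pseudocount of 5, which also put ZNF117 at 0.64.

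The genes furthest below the control included a feedback phosphatase of ERK signalling, secreted factors and their binding proteins. DUSP5, the phosphatase, had 471 CPM in the control and 6.58 CPM in the knockout-labelled library, 71.5-fold lower (59.2 to 87.2). The translation factor EEF1A2 was 94.6-fold lower (144 against 1.52 CPM) and the iron-carrier binding protein LCN2 118-fold lower (36.1 against 0.305 CPM). The activin subunit INHBB was 42.3-fold lower (26.3 to 72.9). IGFBP4, which binds insulin-like growth factors, had 273 and 19.6 CPM (14.0-fold lower; 12.5 to 15.7). CDH12, SEMA6B, PRR9 and EMP1 were also among the 10 lowest. CDH12 rested on 3 counts in the knockout-labelled library (85.7-fold lower; 29.1 to 418).

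Several of the genes furthest above the control encode nuclear RNA-binding proteins. HNRNPM, a splicing regulator, had 79.8 CPM in the control and 564 CPM in the knockout-labelled library (7.07-fold higher; 6.71 to 7.44). SFPQ was 5.62-fold higher (58.8 against 330 CPM) and the RNA helicase DDX39A 6.32-fold. GUCY2C, the intestinal receptor for guanylin, was 9.60-fold higher (1.83 against 17.6 CPM; 6.88 to 13.7). ASCL2, a transcription factor of intestinal stem cells, was 5.54-fold higher (33.8 against 187 CPM; 5.11 to 6.01). NCOA5, HMGN5, SLAMF6 and CTTNBP2 were also among the 10 highest.

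Of 12644 genes compared, 857 (6.78%) were at least 2-fold higher and 719 (5.69%) at least 2-fold lower in the knockout-labelled library. Protein-coding genes made up 750 and 660 of these. At 4-fold the numbers were 34 higher and 113 lower, and at 8-fold 0 higher and 22 lower. These numbers are of the ratio with 1 CPM added, which lowers the ratio of genes that are low in either library, such as GUCY2C and ZNF117. The counting interval of the ratio excluded 1 for all 857 and 719 genes. The size rule and the minimum mean already ensure this at these library totals, so it adds no information. The median log2 ratio of all compared genes was 0.12. The balance of higher and lower genes depended on the scaling: higher genes made up 54.4% of both with library totals (857 against 719), 40.6% with TMM (601 against 879), 38.5% with the upper quartile (574 against 917) and 36.5% with the median of gene ratios (544 against 945). These scalings shift every log2 ratio by -0.12, -0.14 and -0.16, so genes just above the rule lose it. Of 80 genes that the naming rule took and that passed, 11 lost it under at least 1 of these scalings, and all 11 were among the higher genes. A pseudocount of 5 took it from 12 higher and 3 lower genes.

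**Figure D1:**
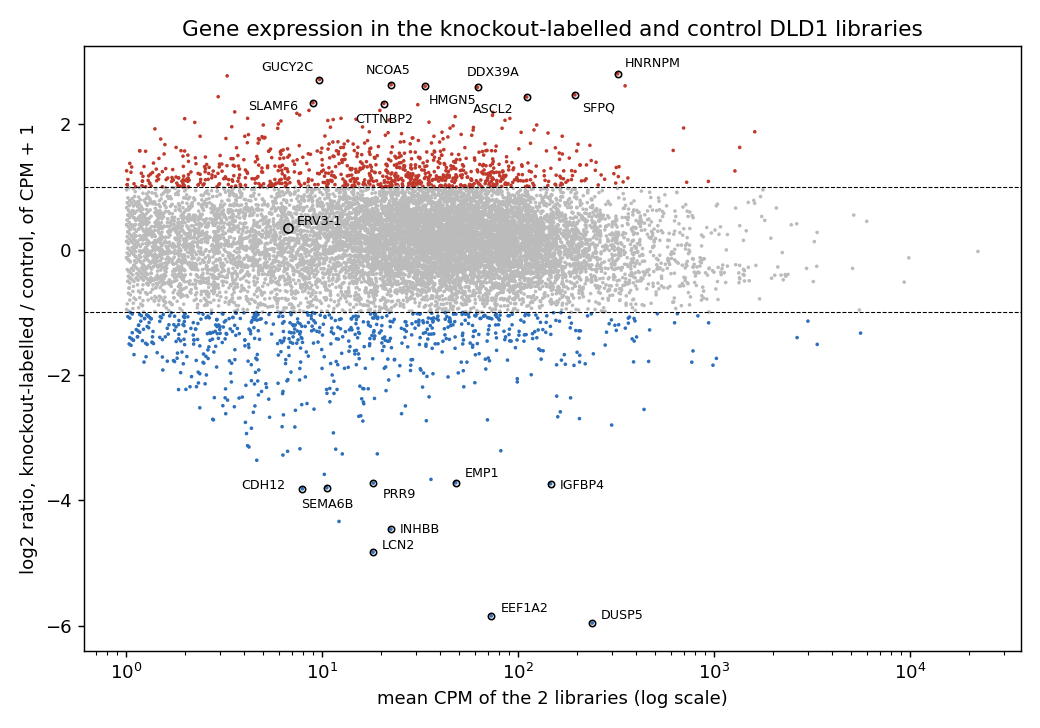
Each point is a gene, with its mean CPM over the 2 libraries on a log axis and its log2 ratio of knockout-labelled to control library (1 CPM added) on the vertical axis. Dashed lines mark the 2-fold rule, which 857 genes passed above and 719 below; genes named in the text from the 10 at each end and ERV3-1 are circled, and the lowest, DUSP5, stands at -5.96.

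Genes of ERK pathway output, YAP/TEAD activity, mesenchymal state and cell migration had lower values in the knockout-labelled library. Of 30 measured ERK output and immediate early genes, 9 were at least 2-fold lower, 0 higher and 21 between, with a median log2 ratio of -0.61 against -0.17 to 0.34 for the central 95% of random lists. After DUSP5, the lowest was MYEOV (148 against 15.1 CPM; 9.79-fold lower). Further members, DUSP6 and the AP-1 subunit FOSL1, were chosen after their values were seen and were 6.89-fold and 6.48-fold lower. The list did not move as a block, as FOS had 10.2 and 12.7 CPM and SPRY2 23.4 and 29.1 CPM. Of 21 YAP/TEAD targets, 8 were lower, 1 higher and 12 between (median -0.65; random lists -0.21 to 0.40). The matricellular gene CTGF was 26.3-fold lower (13.2 to 61.6), ANKRD1 had 184 counts against 1 (138-fold lower; 24.5 to 5478), and DLC1 was 3.57-fold higher.

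Of 19 mesenchymal and EMT genes, 9 were lower, 1 higher and 9 between (median -0.94; random lists -0.25 to 0.43), and 4 were lower with a pseudocount of 5. The median was -0.47 with that pseudocount and -0.46 with no filter on low values, where 27 members were measured. CTGF was among the lowest, and fibronectin (FN1) was 7.69-fold higher from a low level (0.960 against 7.38 CPM; 4.81 to 12.9). Of 25 matrix protease, integrin and migration genes, 6 were lower, 0 higher and 19 between (median -0.67; random lists -0.20 to 0.36). The protease inhibitor TIMP3 was 8.29-fold lower (28.8 against 3.47 CPM) and urokinase (PLAU) 13.8-fold lower (7.71 to 27.0). Of 17 TGF-beta and BMP targets, 6 were lower, 2 higher and 9 between (median -0.32; random lists -0.21 to 0.46). INHBB was the lowest, while TGFB3 (2.64-fold) and the BMP antagonist BAMBI (2.17-fold) were higher. BAMBI lost the rule under each other scaling (0.97 with TMM), and both did with a pseudocount of 5. These lists share members: the EMT list holds 2 measured YAP/TEAD targets, AXL and CTGF.

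DNA replication, WNT target and heat shock genes had higher values in the knockout-labelled library. Of 41 G1/S and replication genes, 17 were at least 2-fold higher, 0 lower and 24 between (median 0.92; random lists -0.10 to 0.32). With TMM 12 were higher, and with the upper quartile or the median of gene ratios 10. The DNA polymerase subunit POLA1 was 3.99-fold higher (18.01 against 71.9 CPM; 3.56 to 4.49) and DNA ligase LIG1 3.03-fold (37.9 against 115 CPM). Of 36 G2/M genes, 3 were higher, 0 lower and 33 between, and the median of 0.28 lay within the range of random lists (-0.13 to 0.29); with each other scaling 2 were higher. CENPF and ASPM, which act at kinetochore and spindle pole, were 3.11-fold and 2.32-fold higher. Of 25 WNT/beta-catenin targets, 8 were higher, 1 lower and 16 between (median 0.75; random lists -0.19 to 0.38). With TMM 7 were higher and 2 lower, and with the upper quartile or the median of gene ratios 6 and 2. Besides ASCL2, the chloride cotransporter SLC12A2 was 3.85-fold higher (288 against 1108 CPM), and KREMEN1, a WNT inhibitor receptor, was 3.496-fold lower. Of 16 heat shock genes, 4 were higher, 0 lower and 12 between (median 0.63; random lists -0.29 to 0.34), with HSP90AA1 3.69-fold higher (687 against 2534 CPM) and HSPB1 2.21-fold. With TMM or the upper quartile 2 heat shock genes were higher, and with the median of gene ratios 1, where HSPB1 stood at 0.99.

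Of 13 mitochondrially encoded genes, 1 passed the rule, CYTB (658 against 2040 CPM; 3.10-fold higher), and 13 had a log2 ratio above 0, although that of ND5 (0.13) turns with the shift of the upper quartile or the median of gene ratios. The list's median was 0.55 (random lists -0.42 to 0.32). Mitochondrial ribosomal RNA, which is not in that list under its own symbols, went the other way, with 0.886% of counts in the control and 0.360% in the knockout-labelled library. Of 8 measured histone genes, 2 were higher, HIST1H4H (10 against 55 counts) and HIST1H2AC (7 against 40 counts), and 6 lay between (median 0.83; random lists -0.50 to 0.57). These low counts make the list depend on the pseudocount: its median was 1.40 with 0.1 and 0.31 with 5, where 0 members passed. Most histone mRNAs lack a poly(A) tail, so their level depends on how the library was made. Of 51 cytosolic ribosomal protein genes, 0 passed the rule in either direction and 46 had a ratio below 0 (median -0.36; random lists -0.28 to 0.13). Nuclear oxidative phosphorylation genes (33 measured) and housekeeping genes (29) had 0 members past the rule, apart from 1 housekeeping gene that was lower with each other scaling. Their medians were 0.23 and 0.03, and the housekeeping median was -0.09 to -0.12 with the other scalings; ATP5B had 968 and 1147 CPM, and GAPDH 3031 and 3667 CPM.

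Epithelial and intestinal genes went both ways. Of 31 junction and keratin genes, 6 were lower, 1 higher and 24 between (median -0.19; random lists -0.21 to 0.31). KRT7 was 5.33-fold lower (28.9 against 5.43 CPM), KRT80 3.03-fold lower, and the desmosome gene PKP3 2.15-fold higher, though under the rule with each other scaling (0.98 with TMM). Of 17 intestinal differentiation genes, 5 were lower, 2 higher and 10 between (median -0.30; percentile 1.39). The trefoil peptide TFF2 was 24.6-fold lower (131 counts against 4) and DPP4 3.62-fold lower, while the intestinal transcription factor CDX2 was 2.998-fold higher (99.5 against 298 CPM) and PHGR1 2.09-fold, which lost the rule under each other scaling, where 1 was higher and 7 lower. The list's place outside the range of random lists was lost in 6 of 9 alternatives, with percentiles from 2.5 (TMM) to 19.3 (a minimum mean of 5 CPM). Of 13 stem cell genes, 2 were higher, 3 lower and 8 between (median 0.12; percentile 53.8), among them LGR5 (2.24-fold higher, though 0.99 on the log2 scale with the upper quartile) and ALDH1A3 (7.75-fold lower).

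Of 30 NRF2 and antioxidant genes, 4 were lower, 0 higher and 26 between (median -0.32; random lists -0.24 to 0.27), with ABCC3 4.14-fold and GPX3 3.94-fold lower. The list was divided, with 12 members above 0 and 18 below. With each other scaling 6 were lower, and with a pseudocount of 5, 2 were lower, GPX3 not among them. Of 34 unfolded protein and integrated stress response genes, 4 were lower and 3 higher (percentile 13.4). The ER chaperone HSPA5 was 3.33-fold lower (1579 against 474 CPM) and HERPUD1 3.24-fold lower, while ATF5 (3.46-fold) and CRELD2 (2.77-fold) were higher. Of 32 hypoxia and glycolysis genes, 5 were lower and 0 higher (percentile 16.2), with 7 lower under each other scaling; the glucose transporter SLC2A1 was 3.56-fold and BNIP3L 3.22-fold lower. Of 31 cholesterol and fatty acid synthesis genes, 4 were higher and 3 lower (percentile 51.0), and 2 were higher with each other scaling. MSMO1 was 2.80-fold lower (102 against 36.6 CPM), and LSS, which makes lanosterol, was 3.37-fold higher (3.89 against 13.1 CPM).

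Of 27 p53 targets, 3 were higher and 1 lower (percentile 47.3): GDF15 was 3.46-fold lower (718 against 208 CPM), SESN2 2.68-fold and AEN 2.66-fold higher. With each other scaling 2 were higher and 2 lower. Of 30 apoptosis genes, 2 were higher and 2 lower (percentile 42.4). BMF (4.14-fold) and BCL2L1 (3.13-fold) were lower, CASP6 (2.22-fold) and BCL2L11 (2.14-fold) higher. With each other scaling, and with a pseudocount of 5, 0 were higher; CASP6 stood at 0.98 and BCL2L11 at 0.93 with TMM. Of 28 interferon-stimulated genes, 2 were higher and 2 lower (percentile 8.80), with UBE2L6 3.98-fold and ISG20 4.79-fold lower. With each other scaling 0 were higher, and with a pseudocount of 5, 0 were higher and 1 lower. Of 21 NF-kB and inflammatory genes, 6 were lower and 1 higher (percentile 36.7); IL32 was 7.54-fold lower after LCN2, and CXCL2, the higher member, had 12 counts against 39 and lost the rule with a pseudocount of 5. Of 10 antigen presentation genes, 1 was lower, HLA-B (13.8 against 5.00 CPM), and its symbol stands on 6 rows, so its value is uncertain; it lost the rule with a pseudocount of 5.

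Across the 27 lists with at least 5 measured members, the median of 13 lay outside the central 95% of random lists, 8 below and 5 above, where 1.35 would do so for lists drawn at random. Among the 8, some were divided, as the bootstrap 95% interval of the median over members included 0. These were the NRF2 (-0.779 to 0.328), TGF-beta and BMP (-1.436 to 0.265) and intestinal (-1.288 to 0.505) lists. Few markers of other cell types reached a mean of 1 CPM. Of 16 fibroblast markers 1 was measured (PDGFRB, 4.66 and 2.32 CPM), of 24 blood and immune markers 3 (CORO1A the highest, 36.1 and 65.6 CPM), and of 12 endothelial markers 2 (ESAM the highest, 9.10 and 6.16 CPM). Of 16 markers of other epithelial lines 2 were measured (PAX8 the highest, 7.22 and 5.67 CPM). None of these passed the 2-fold rule with 1 CPM added. Without it, PDGFRB was 2.01-fold lower (1.37 to 3.003) and GATA3 2.25-fold higher (1.17 to 4.47), from 16 counts against 27, and GATA3 passed with a pseudocount of 0.1 (1.07).

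**Figure D2:**
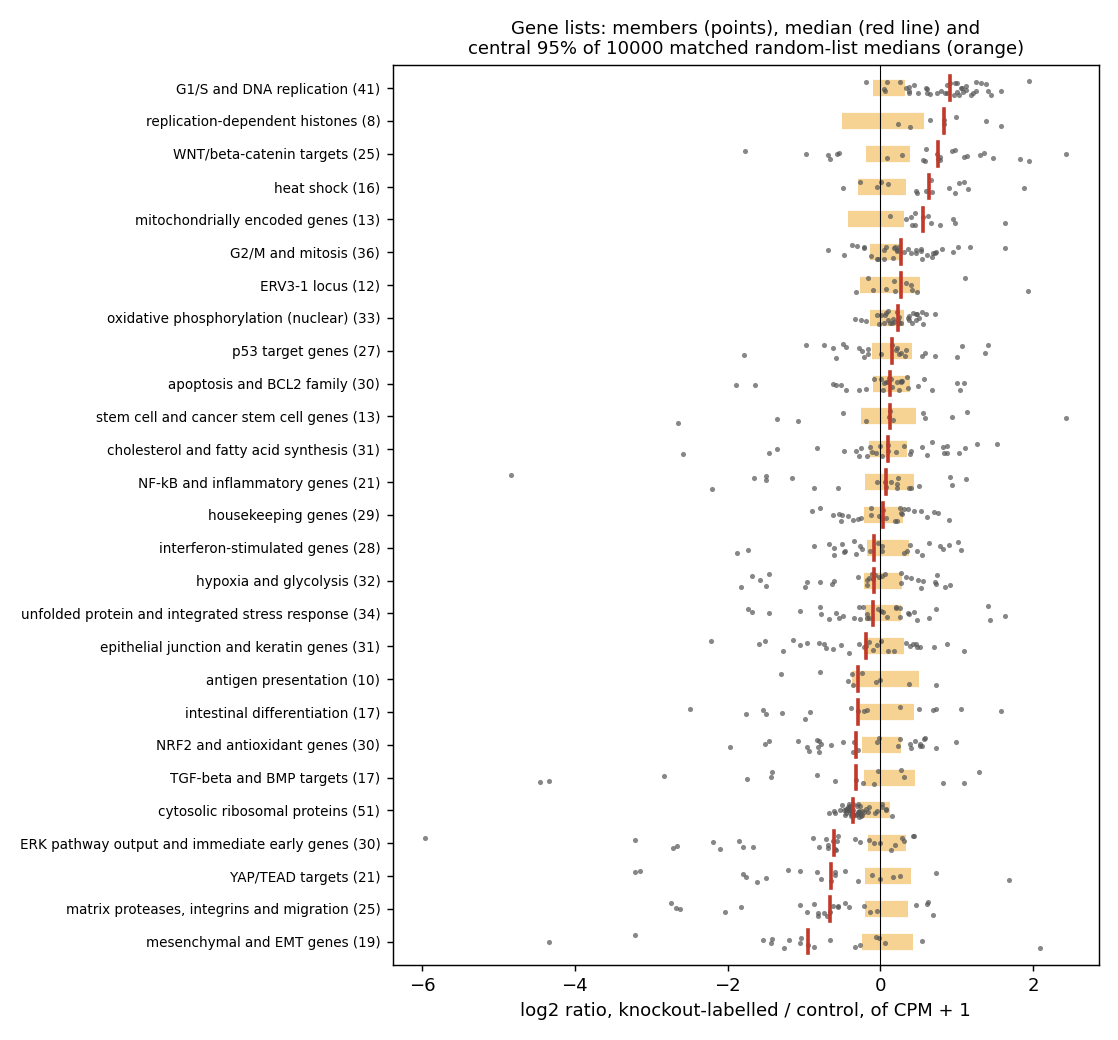
For each gene list fixed beforehand with at least 5 measured members, the points are members' log2 ratios (knockout-labelled over control library, 1 CPM added) and the marked median is set against the central 95% of medians of random lists matched on expression. The G1/S list has a median of 0.92 and the mesenchymal and EMT list one of -0.94, which was -0.47 with a pseudocount of 5.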

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

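The omission of ribosomal RNA, of genes that are not protein-coding, of symbols on several rows and of chromosome 10 were alternatives chosen after the data had been seen; the others were planned. ERV3-1 was not lower in the knockout-labelled library under any alternative run, with log2 ratios of 0.20 to 0.39. Against 857 genes at least 2-fold higher and 719 lower, a pseudocount of 5 gave 426 and 371, which follows from its construction, since it shrinks the ratios of low genes. The 1.5-fold rule gave 2567 and 1674 and the 3-fold rule 118 and 229, as a looser or stricter rule must give more or fewer. Scaling by the median of gene ratios gave 544 higher, through its shift of every log2 ratio by -0.16. The other alternatives stayed within 1.5 times both counts, with the upper quartile (574 higher) and a mean of at least 5 CPM (487 lower) nearest to that limit. Between 12 and 13 lists lay outside the range of random lists. Intestinal differentiation returned inside it in 6 of 9 alternatives: a pseudocount of 5 (percentile 6.03), no filter (11.6), a mean of at least 5 CPM (19.3), TMM (2.5), the upper quartile (2.64) and the median of gene ratios (3.04). Junction and keratin genes left it with no filter (2.45) and a mean of at least 5 CPM (2.48). The cause was not tested. Of 558 values of 93 named genes under alternatives, 0 reversed and 248 lay outside the counting interval. That interval is of the ratio without a pseudocount, so the main value of a gene with few counts can already lie outside it. LCN2 with TMM (-4.90, against -4.83 with library totals) was among the 248, so this number does not measure movement. No reversal was possible for these 93, as a pseudocount keeps the sign and each ratio above 0 was larger than the shifts. ERV3-1 was followed apart, and ERV3-1-ZNF117 was not among the 93. The log2 ratio of ERV3-1-ZNF117 (0.07) is smaller than the shift of each other scaling (-0.12 to -0.16), so its direction turns with them. Of 243 list medians 15 moved, those of histones the furthest (0.31 to 1.40), and 13 medians of 6 lists changed sign (NF-kB, apoptosis, cholesterol, housekeeping, hypoxia and stem cell genes), 0 of them from lists outside the range of random lists. No leave-one-out and no paired analysis was possible because each group has 1 library. Depth limits genes near the floors of 0.137 and 0.183 CPM, such as ANKRD1 and CDH12.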

Other observations

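The gene lists and the chromosome comparison in this part were chosen after the data had been seen, so their place among random lists describes what was noticed and is no independent evidence. Of the tests, those of whole-chromosome copy number, of handling and of nuclear RNA were chosen only after the result was seen.

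Of 11 SR splicing factors, 7 were at least 2-fold higher, 0 lower and 4 between (median log2 ratio 1.24; random lists -0.30 to 0.44). SRSF6 had 60.7 and 223 CPM (3.68-fold) and SRSF2 54.0 and 177 CPM (3.28-fold), whereas SRSF4 had 132 and 101 CPM. Of 29 hnRNP genes, 6 were higher, 0 lower and 23 between (median 0.46; random lists -0.28 to 0.25). Of 52 genes of rRNA synthesis and ribosome assembly, 20 were higher, 1 lower and 31 between (median 0.91; random lists -0.08 to 0.28). POLR1A, the large subunit of RNA polymerase I, was 4.28-fold higher, UTP20 4.55-fold, NOP56 3.54-fold and nucleolin (NCL) 2.39-fold (752 against 1798 CPM). The ribosomal protein genes, with a median of -0.36, stood on the other side.

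Of 364 ZNF genes, 50 were higher and 7 lower (median 0.39; random lists 0.07 to 0.21), and with the other scalings 28 to 32 were higher. Of 20 KLF and keratin genes, a list joined from both families after their values were seen, 10 were lower and 0 higher, while the junction and keratin list fixed beforehand lay inside its random range (median -0.19, percentile 3.47). The latter list left that range with no filter (2.45) and with a minimum mean of 5 CPM (2.48). The keratin pair KRT8 (4138 against 1876 CPM; 2.21-fold lower) and KRT18 (4967 against 1741 CPM; 2.85-fold lower) is among the most abundant of these, and both genes have pseudogenes that can share their reads.

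Genes on chromosome 10 were lower as a group. Over 403 genes of at least 5 CPM the median log2 ratio was -0.19 (bootstrap 95% interval -0.25 to -0.13) against 0.14 for the other chromosomes, and the next lowest of 23 chromosomes was 17 at -0.05. The tables argue against GC content, transcript length or expression level, since the median lay -0.33 from the mean of matched gene sets, below the lowest of 10000. Lower copy number of the whole chromosome may contribute and stays open: 6 of the 7 parts of 20 Mb had medians below 0, but the part from 40 to 60 Mb stood at 0.26 with an interval (0.12 to 0.47) that includes the median of other genes. DNA copy number was not analysed here.

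Lower ERK output in the knockout-labelled library is a hypothesis for DUSP5, DUSP6, FOSL1 and MYEOV. It was not tested, as ERK activity was not measured here, and FOS and SPRY2 of the same list were not lower. The tables argue against the chromosome 10 shift as the source of the lower ERK list, since 1 of the 9 members at least 2-fold lower, DUSP5, lies there. Handling at harvest could contribute and stays open: 13 immediate early genes raised by handling had a median of -0.60 with an interval (-0.88 to 0.01) that decides neither way. That median lay below the range of random lists (-0.27 to 0.47). The ERK list itself holds immediate early genes, so this test cannot tell handling from lower ERK output. A difference between single cultures or clones unrelated to the knockout stays open as well, with 1 library per group, and so does an effect of the HERV-R edit.

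The higher SR splicing factor genes may reflect a difference in RNA fractions as well as in the cells. The tables argue against GC content, transcript length or expression level. Over 10095 genes the log2 ratio had Spearman correlations of only 0.001, 0.03 and -0.07 with these. Matched gene sets had a mean median of 0.01. The SR median lay 1.23 above that mean and above the highest of 10000 (0.70). As the list was chosen after the data had been seen, that place is no independent evidence. A larger share of nuclear RNA stays open. The 7 nuclear long non-coding RNAs had a median of 0.26, within the range of random lists (-0.45 to 0.55). It lay below the interval of the SR genes (0.34 to 1.67), but its own interval (-0.14 to 0.74) overlaps that interval. NEAT1 had 110 and 125 CPM. A biological effect of the knockout was not separable from a difference between the 2 cultures.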
